A study of Arabidopsis thaliana with 6 samples.

How the data were processed

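Whole seedlings of wild-type Arabidopsis thaliana were sampled at 6 h on MS medium, a standard plant culture medium, either alone (control) or with 20 mM yttrium oxide nanoparticles. Total RNA was extracted with Trizol and sequenced with Illumina libraries, per the labels' protocols. There were 3 libraries in each group, and groups were taken from the treatment label. Nothing in the labels says that the 3 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

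The authors deposited 1 table of FPKM values (fragments scaled to gene length and to library size) for 32948 genes in the 6 libraries. HISAT2 2.0.5 and the TAIR10 genome build are named per the submitters' processing notes. The counting program, the annotation release, the use of strand and any filter are not given in the sources used here. The table pairs 13415 gene IDs with names and holds 115 genes marked as outside the annotation. Of the IDs, 32548 matched the TAIR10.1 reference annotation, where 99.95% of them had the same start and end, and missing gene names were taken from that reference. The authors' deposited comparison table lists 2104 genes with a signal per library (read counts divided by 1 size factor per library), group means, a log2 fold change, a p-value and an adjusted p-value. All of its adjusted p-values were under 0.05 and all of its absolute log2 fold changes above 1, per the file's own values. Its fold changes are treated over control.

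FPKM times gene length gave whole multiples of 1 step per library for 100% of values (within 0.01 of a whole number), so read counts were recovered. Recovered totals were 19635539, 20179763 and 23374306 reads in controls 1, 2 and 3, and 21790611, 22089042 and 19314683 in treated libraries 1, 2 and 3. The library size the authors divided by was 0.993 to 1.02 times these totals. A count of 0 allows up to 3 reads, which for a gene of 1 kb is 0.129 to 0.154 FPKM. That limit covers counting error only, since reads copied by PCR are not independent molecules. No pair of libraries was a repeat of another: within groups the chi-square per degree of freedom over genes lay between 12.3 and 34.9.

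The test was fixed before the data were examined. Genes with a mean FPKM of at least 1 over the 6 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust, 2-sided) on log2(FPKM + 1), with treatment as the only term. Benjamini-Hochberg adjusted p under 0.05 was the threshold. Changes are treated minus control on the log2(FPKM + 1) scale, which understates the change of low genes, with the model's standard error (SE). FPKM values are mean ± SD over 3 libraries.

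Before the data were examined, 33 gene lists with 609 genes were fixed from textbook knowledge, including markers of the tissues a seedling sample can hold. All 609 genes were found by their gene ID, 601 of them under the name used in the list, and none was dropped. The 32 lists with at least 5 tested members were tested with camera, which compares a list with all other genes, at a preset correlation of 0.01. Alternatives were camera with an estimated correlation and fry, which tests whether the members of a list move one way on balance. Single members were also adjusted over the list alone. Named genes followed a rule fixed in advance: the 8 largest rises and the 8 largest falls among genes past the threshold with non-overlapping groups, a mean FPKM of at least 5 and a symbol; up to 3 members in the list's direction, by adjusted p, for each list camera called; and 1 member for each other list. Any further gene named below was chosen after its values were seen.

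The limma step was tested on simulated counts for this comparison with 18561 genes in the step. It recovered 14.3% of genes changed 1.5-fold, 55.1% of those changed 2-fold and 98.0% of those changed 4-fold, with 10 false calls among 119. The real data gave 2696 calls, so the threshold was less strict there in unadjusted p, and these shares do not carry over. In 20 simulations camera with the preset correlation called 5 of 580 unshifted lists and all 60 lists shifted 1.5-fold. With the estimated correlation it called 0 of the 580 and all 60. The simulated genes were independent, while the correlation estimated within the 32 real lists had a median of 0.280 and reached 0.791, so the rate of 5 in 580 does not carry over to them. The 9 other splits of the real libraries into 3 and 3 called 8 to 18 of the 32 lists with the preset correlation and 0 genes. Each of them mixes control and treated libraries, so part of the treatment difference stays between the groups and the rest lies within them. They therefore give no rate of false calls.

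Alternatives fixed in advance were other pseudocounts (0.1 and 0.5), other filters, other scalings of the libraries, organelle genes left out, other variance settings, array weights, a replicate block, each library left out in turn, and edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 on the recovered reads. Corrections for exonic GC content and gene length were added after seeing the data. Overlaps of gene spans and figures used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Without a stated use of strand, reads of a gene and of an overlapping gene on the other strand cannot be told apart, and named genes with at least 20% of their span inside such a gene are marked as uncertain, a limit set after the values were seen.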

Results

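The series asks how Arabidopsis seedlings respond to the toxicity of yttrium oxide nanoparticles, particles of a rare-earth metal oxide. Messenger RNA abundance was compared between 3 control libraries and 3 libraries of seedlings treated with 20 mM of the particles, all at 6 h. Library totals recovered from the deposited values were between 19314683 and 23374306 reads. Chloroplast-encoded genes took 0.0138 ± 0.000591% of reads in controls and 0.0156 ± 0.00211% in treated libraries (SD, n = 3 each). The first principal component of log2(FPKM + 1) held 68.4% of the variance and separated the groups. Treated library 2 lay nearer to the controls on it, at 25.1 against 48.2 and 40.7 for treated libraries 1 and 3, and stood apart on the second component at -29.8.

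In the treated seedlings many root-expressed genes were lower in relative abundance, and many genes of phosphate shortage, low sugar and defence were higher. Of 18614 genes tested, 2696 (14.5%) passed the threshold, 1502 higher and 1194 lower in treated seedlings, and 1149 changed at least 2-fold on the log2(FPKM + 1) scale. All 2696 had groups that did not overlap, which a call with 3 libraries per group makes likely by itself. Over all tested genes, 35.6% had non-overlapping groups. Chance gives 10% for a single gene, but genes vary together, so this share is not a test. The largest rise among named genes was that of ASN1 (AT3G47340, chromosome 3, 17437840 to 17441431, TAIR10), an asparagine synthetase induced by darkness, from 0.239 ± 0.0929 to 43.2 ± 16.0 FPKM (log2 change 5.10, SE 0.232, limma adjusted p = 1.62e-05). It was followed by DRMH1, a dormancy-associated protein homologue (4.24), BHLH100 (4.0), SPX3 (3.80), the purple acid phosphatase gene PAP14 (3.80), the transcription factor gene BZIP1 (3.68), the beta-glucosidase gene BGLU30 (3.64) and BT5 (3.39). The largest falls were those of AIR1B (-4.66), the lipase-like gene GLL22 (-4.44), the ammonium transporter gene AMT1-3 (-4.27), the arsenate reductase gene HAC1 (-4.07), the phosphoenolpyruvate carboxylase gene PPC3 (-3.87), AIR1 (-3.84), the jacalin lectin gene JAL10 (-3.66) and the nitrate transporter gene NRT2.1 (-3.66). Camera called 17 of 32 gene lists, 13 upward and 4 downward, and fry called 11. With an estimated correlation camera called 0, with 1 list at an unadjusted p under 0.05. The preset correlation also called 8 to 18 lists in the 9 other splits of the libraries into 3 and 3, in which 0 genes were called. Those splits mix control and treated libraries and hold part of the treatment difference, so neither count measures chance. AIR1 and AIR1B are uncertain, since 92.9% and 67.3% of their spans lie inside a gene on the other strand. The treated means of AIR1B (0.119 FPKM) and JAL10 (0.0117 FPKM) lie under the limit for a count of 0 in a gene of 1 kb. So does the control mean of PAP14 (0.115 FPKM), and the size of these changes is uncertain. Without control 1 the number of genes called was 1340, and without control 2 it was 1555. Higher calls fell to 889 without treated library 1, and edgeR on the recovered reads called 3418 genes, 1924 of them at least 2-fold.

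**Figure D1:**
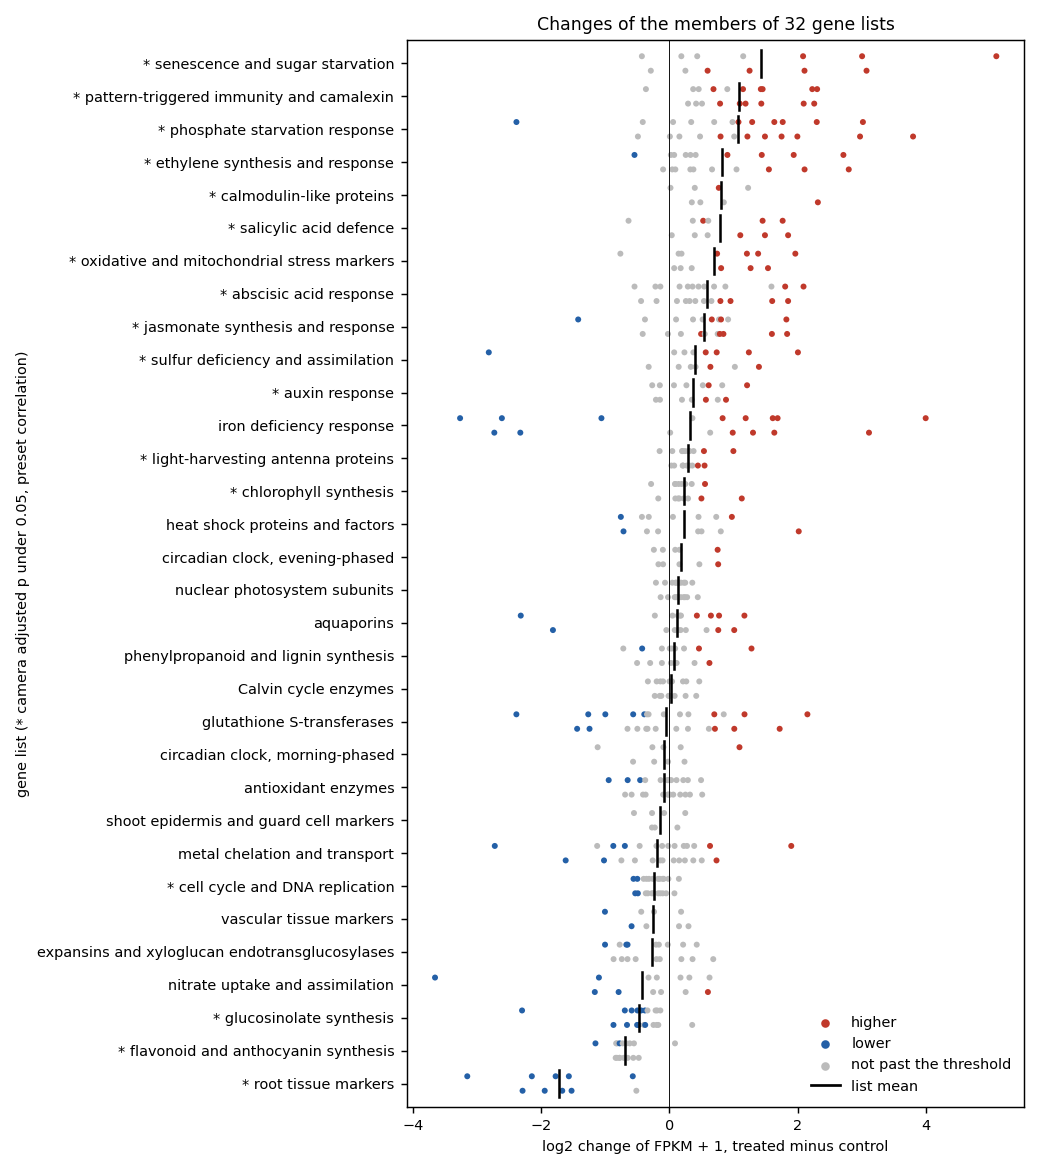
Each point is a tested member of 1 of 32 gene lists. The horizontal axis is its log2 change of FPKM + 1 (treated minus control), colours mark members past the limma threshold, and black lines are list means. Root tissue markers had the lowest mean (-1.72) and the senescence and sugar starvation list the highest (1.42), while members of the iron deficiency list lay far to both sides.

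Root tissue markers fell. Of 10 tested members 9 were lower and 0 higher, and 9 were lower when adjusted over the list alone (camera adjusted p = 4.68e-11; adjusted p = 0.0571 with an estimated correlation). CASP1 (AT2G36100, chromosome 2, 15159591 to 15160799), a scaffold protein of the Casparian strip in the root endodermis, went from 9.27 ± 0.518 to 0.154 ± 0.0841 FPKM (log2 change -3.16, SE 0.132, limma adjusted p = 8.08e-06). CASP2 went from 3.13 ± 0.516 to 0.0650 ± 0.0330 FPKM, and the root hair genes LRX1, EXPA7 and EXPA18 from 2.05, 2.73 and 4.1 FPKM to 0.0113, 0.0835 and 0.0122. The treated values of CASP2 and these root hair genes lie under the limit for a count of 0 in a gene of 1 kb (0.129 to 0.154 FPKM). That of CASP1 lies at its upper end. All of these treated values are small. They rest on few reads, and the size of these falls is uncertain. BGLU23, an abundant root beta-glucosidase, fell less, from 2135 ± 276 to 479.3 ± 33.5 FPKM, and the phosphate exporter gene PHO1 from 21.1 to 13.9 FPKM. MYB36 had a log2 change of -0.52 and an adjusted p of 0.170. Markers of the shoot epidermis and guard cells had 0 of 7 members past the threshold by limma, also when adjusted over the list alone (camera adjusted p = 0.361). At an unadjusted p under 0.05 there were 2, and edgeR called 0 and DESeq2 1 of these 7. In the vascular list 2 of 8 members fell, XCP1, a xylem protease gene, by 1.01 on the log2 scale (SE 0.210), and the cellulose synthase gene CESA8 by 0.59 (camera adjusted p = 0.176, but fry adjusted p = 0.0198, downward). The 3 tested seed storage genes CRA1, CRU3 and OLEO2 all fell, CRA1 from 23.5 to 1.84 FPKM, and 3 members were too few for camera.

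Genes of phosphate starvation rose. Of 24 tested members 13 were higher, 1 lower and 10 not past the threshold, and 16 were higher and 3 lower when adjusted over the list alone (camera adjusted p = 5.92e-07; adjusted p = 0.465 with an estimated correlation). SPX3 (AT2G45130, chromosome 2, 18606410 to 18607853), a phosphate-status regulator, went from 0.498 ± 0.0157 to 20.6 ± 6.56 FPKM (log2 change 3.80, SE 0.222, limma adjusted p = 2.60e-05). The phosphatase gene PEPC1 rose by 3.02 (SE 0.205) and the non-coding RNA AT4 by 1.64 (SE 0.105). IPS1, another such RNA, and the lipid-remodelling genes SQD2, MGD3 and PLDZ2 also rose, by 2.0, 1.75, 2.3 and 1.49. The member that fell was PHT1;1, a phosphate uptake transporter of roots, from 174 to 32.8 FPKM, alongside the fall of root tissue markers (list mean -1.72).

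The sulfur list had 6 members higher, 1 lower and 8 not past the threshold among 15, with 9 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.00621; adjusted p = 0.547 with an estimated correlation). SDI1, a repressor induced by sulfur shortage, rose from 18.8 ± 6.27 to 80.6 ± 31.9 FPKM, SDI2 (AT1G04770) by 1.24 and the vacuolar sulfate exporter gene SULTR4;2 by 0.64 on the log2 scale. SDI2 is uncertain to the extent that 27.3% of its span lies inside a gene on the other strand. SULTR1;2, the sulfate uptake transporter of roots, fell from 56.5 to 7.26 FPKM. In the nitrate list 1 of 13 members rose and 4 fell (2 and 4 when adjusted over the list alone; camera adjusted p = 0.133, but 0.0425 without control 2 and 0.0397 without treated library 3). NRT2.1 went from 48.5 ± 10.8 to 3.14 ± 1.98 FPKM, and NRT1.1, NRT1.5 and the nitrite reductase gene NIR1 fell by 1.16, 1.1 and 0.79, while HHO3 rose by 0.60. These falls stood beside that of the root tissue markers.

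Iron genes split into 2 directions. Of 17 tested members of the iron deficiency list, 9 rose, 5 fell and 3 did not pass the threshold, with the same numbers when adjusted over the list alone, and camera did not call the list (adjusted p = 0.125; 0.0471 without control 3 and 0.00527 without treated library 3). The regulators BHLH100, BHLH101 and BHLH38 rose by 4.0, 3.11 and 1.64, the peptide genes IMA1 and IMA2 by 1.69 and 1.61, and BTS, PYE, FRO3 and the phloem transporter gene OPT3 by 1.3, 0.99, 1.19 and 0.83. BHLH38 is uncertain, with 31.9% of its span inside a gene on the other strand. The members that fell are known mainly from roots. The nicotianamine synthase gene NAS2 went from 11.2 ± 1.84 to 0.265 ± 0.201 FPKM (limma adjusted p = 1.71e-05), the transcription factor gene FIT from 12.4 to 1.2, the iron transporter gene IRT1 from 12.1 to 0.557, the reductase gene FRO2 from 1.76 to 0.258 and the coumarin synthesis gene F6H1 from 38.0 to 6.93. In the list of metal chelation and transport 3 of 27 members rose and 5 fell (5 and 8 when adjusted over the list alone; camera adjusted p = 0.361, but fry called it downward at 0.00780). The zinc transporter gene ZIP3 went from 8.31 ± 0.817 to 0.405 ± 0.102 FPKM, and the ferritin genes FER1 and FER3, whose proteins store iron, from 205 and 92.5 to 68.2 and 45.7. FER1 is uncertain, with 63.6% of its span inside a gene on the other strand. The vacuolar transporter gene ZIF1 rose from 11.9 to 47.7 FPKM.

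**Figure D2:**
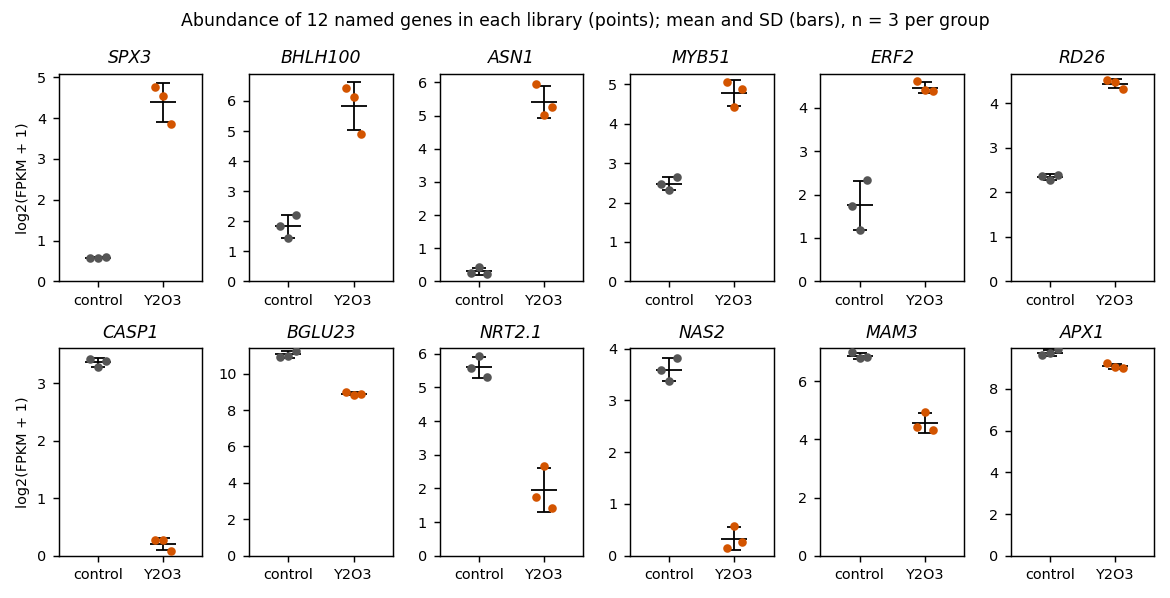
Points are the log2(FPKM + 1) of 12 genes in each of the 3 control and 3 treated libraries, and bars are group means with SD. The upper genes were higher in all 3 treated libraries than in any control, as SPX3 (0.498 against 20.6 FPKM), and the lower genes below every control, as CASP1 (9.27 against 0.154 FPKM).

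Senescence and sugar starvation genes rose as well. Among 13 tested members 7 were higher, 0 lower and 6 not past the threshold, and 8 were higher when adjusted over the list alone (camera adjusted p = 1.50e-05; adjusted p = 0.421 with an estimated correlation). Besides ASN1, the members named by the rule were SEN1 (AT4G35770), from 0.173 ± 0.183 to 9.40 ± 4.06 FPKM, and BCAT2, an enzyme of branched-chain amino acid breakdown, from 1.05 ± 0.169 to 8.14 ± 3.05 FPKM. DIN10 rose from 14.1 to 133 FPKM and the senescence regulator NAP from 0.0759 to 3.74 FPKM. The control value of NAP lies under the limit for a count of 0 in a gene of 1 kb. Clock genes were read as a check of the sampling hour. In the morning-phased list 1 of 9 members rose (RVE1, log2 change 1.09) and in the evening-phased list 2 of 10 (TOC1, 0.76, and PRR5, 0.75), with the same numbers when adjusted over each list alone, and camera called neither (adjusted p = 0.691 and 0.367). CCA1, LHY and GI had log2 changes of -0.24, -0.57 and -0.10 with adjusted p of 0.479, 0.111 and 0.725.

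Defence genes rose in several lists. In the list of pattern-triggered immunity and camalexin, the responses to microbial patterns and the main Arabidopsis phytoalexin, 12 of 19 members were higher and 0 lower (15 and 1 when adjusted over the list alone; camera adjusted p = 1.01e-08; adjusted p = 0.421 with an estimated correlation). The transcription factor genes MYB51, WRKY53 and WRKY40 rose by 2.3 (SE 0.177), 2.1 (SE 0.168) and 2.23 (SE 0.210), and the oxidase gene RBOHD by 0.69. WRKY53 is uncertain to the extent that 21.1% of its span lies inside a gene on the other strand. Salicylic acid defence had 6 of 12 members higher and 0 lower (8 and 0 when adjusted over the list alone; camera adjusted p = 0.000217; adjusted p = 0.465 with an estimated correlation). CBP60G rose by 1.77, PBS3 by 1.49 and WRKY70 by 1.85, whereas the late marker PR5 had a log2 change of -0.64 with an adjusted p of 0.227 and PR1 was listed at 0 in every library. Jasmonate genes were higher in 8 of 20 cases and lower in 1 (12 and 1 when adjusted over the list alone; camera adjusted p = 0.000217; adjusted p = 0.465 with an estimated correlation). LOX4, JAZ7 (AT2G34600) and AOC1 rose by 1.84, 1.83 and 1.6, and VSP1 fell by 1.42. For ethylene 7 of 20 members rose and 1 fell, and 8 and 1 did when adjusted over the list alone (camera adjusted p = 0.000196, and 0.465 with an estimated correlation). The response factors ERF2 (2.72), ERF5 (2.11) and ERF6 (2.80) led the rises, while the ACC oxidase gene ACO1 fell by 0.55. Other ethylene response members, ETR2, ERS1, ERS2, EBF1 and EBF2, did not pass the threshold (limma adjusted p = 0.151, 0.586, 0.144, 0.731 and 0.266).

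Markers of oxidative and mitochondrial stress were higher in 7 of 13 cases and lower in 0 (7 and 1 when adjusted over the list alone; camera adjusted p = 0.000711; adjusted p = 0.465 with an estimated correlation). SOT12 went from 6.75 ± 1.64 to 19.0 ± 1.67 FPKM, OM66 (AT3G50930), a protein of the outer mitochondrial membrane, from 15.6 ± 3.92 to 38.5 ± 6.91, and the zinc finger gene ZAT10 from 32.8 ± 15.2 to 122.7 ± 13.4. AOX1A, UGT74E2, NAC013, OXI1 and NAC017 did not pass the threshold, with log2 changes of 0.35, 0.19, 0.18, 0.14 and 0.07. Their limma adjusted p were 0.225, 0.593, 0.487, 0.758 and 0.671. The member lower when adjusted over the list alone was NDB2 (-0.77). Of 26 antioxidant enzyme genes limma called 0 higher and 3 lower, also when adjusted over the list alone (camera adjusted p = 0.440), and the 3 were APX1, a cytosolic ascorbate peroxidase (855 to 543 FPKM), SAPX and DHAR2. At an unadjusted p under 0.05 there were 4 of the 26 higher, and edgeR called 1 and DESeq2 2 higher. Glutathione S-transferases went both ways, with 6 of 27 higher and 7 lower (6 and 9 when adjusted over the list alone; camera adjusted p = 0.420). GSTU25 fell from 35.1 ± 4.34 to 5.89 ± 0.906 FPKM and GSTU12 rose from 0.838 to 7.64. Members of this family have close copies that can share reads, so single members are uncertain. Calmodulin-like genes were higher in 2 of 8 cases, CML12 by 2.32 and CML38 by 0.77 (6 when adjusted over the list alone; camera adjusted p = 0.00302; adjusted p = 0.465 with an estimated correlation). CML12 is uncertain to the extent that 31.0% of its span lies inside a gene on the other strand. Heat shock genes had 2 of 14 members higher and 2 lower (6 and 2 when adjusted over the list alone; camera adjusted p = 0.367, but 0.0364 with no filter), with HSP17.6C rising from 4.55 ± 0.706 to 22.4 ± 8.05 FPKM and HSP70-4 falling from 94.7 to 57.3.

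Abscisic acid genes were higher in 6 of 25 cases and lower in 0 (7 and 0 when adjusted over the list alone; camera adjusted p = 0.000711; adjusted p = 0.489 with an estimated correlation). The transcription factor gene RD26 rose by 2.09 (SE 0.110, limma adjusted p = 1.71e-05), the dehydrin gene LTI30 (AT3G50970) by 1.85 and HB-7 (AT2G46680) by 1.6. RD29A and RAB18 had log2 changes of 0.26 and 0.40 with adjusted p of 0.695 and 0.611. Without treated library 2 the camera adjusted p of this list was 0.172. Auxin response genes were higher in 4 of 15 cases and lower in 0 (6 and 0 when adjusted over the list alone; camera adjusted p = 0.0229; adjusted p = 0.421 with an estimated correlation), among them IAA2 (1.21), GH3.5 (0.88) and SAUR21 (0.57). That list lost its call with a minimum mean of 5 FPKM (camera adjusted p = 0.101) and with no filter (0.0652). Among aquaporins 6 of 19 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.0581, but 0.0218 without control 3, and between 0.00998 and 0.0498 under 6 alternatives with all libraries, the lowest with a minimum mean of 5 FPKM). TIP4;1 (AT2G25810) went from 7.71 ± 1.06 to 0.771 ± 0.417 FPKM and PIP2;4 from 4.76 to 0.619, while PIP1;2 and TIP2;1 rose from 208 and 125 to 359 and 278. Of the TIP2;1 span 26.3% lies inside a gene on the other strand, so its value is uncertain.

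Glucosinolate synthesis fell. These sulfur-rich defence compounds are typical of the cabbage family, and 11 of 20 tested members were lower and 0 higher (13 lower and 1 higher when adjusted over the list alone; camera adjusted p = 4.27e-07; adjusted p = 0.465 with an estimated correlation). MAM3, a chain-elongation enzyme, went from 116 ± 8.31 to 23.2 ± 5.90 FPKM (log2 change -2.3, SE 0.168), CYP79F2 fell by 0.87 and BAT5 (AT4G12030) by 0.70. Among flavonoid and anthocyanin genes 2 of 17 fell and 0 rose (1 lower when adjusted over the list alone; camera adjusted p = 0.000217; adjusted p = 0.489 with an estimated correlation). The members that fell were TT7 (AT5G07990), from 35.1 ± 1.90 to 16.0 ± 5.89 FPKM, and the regulator MYB12, whose call was lost with edgeR (adjusted p = 0.0574; range over the alternatives other than left-out libraries up to 0.0733). The list median was -0.73. Phenylpropanoid and lignin genes had 3 of 17 members higher and 1 lower, also when adjusted over the list alone (camera adjusted p = 0.691), with CCR2 rising by 1.28. Of the expansins and xyloglucan endotransglucosylases, which loosen and remodel cell walls, 3 of 18 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 0.0738, but 0.0107 without control 2, 0.0117 without treated library 1, 0.0358 with a minimum mean of 5 FPKM and 0.0466 with the length correction), EXPA10 by 0.65.

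Few photosynthesis genes passed the threshold. Light-harvesting antenna genes were higher in 4 of 19 cases and lower in 0, also when adjusted over the list alone (camera adjusted p = 0.000711; adjusted p = 0.478 with an estimated correlation). LHCB1.4 (AT2G34430) went from 217.5 ± 18.6 to 441.1 ± 93.1 FPKM, LHCB2.2 from 610 ± 26.6 to 894 ± 79.5 and LHCB2.1 from 768 ± 34.7 to 1118 ± 109. Antenna genes of the same type, such as LHCB2.1 and LHCB2.2, are close copies, so the split of reads between them is uncertain. Chlorophyll synthesis had 3 of 16 members higher and 0 lower, also when adjusted over the list alone (camera adjusted p = 0.0200; adjusted p = 0.489 with an estimated correlation), namely PORB (1.13), HEMB1 (0.56) and CHLM (0.50). This list lost its call without control 1, control 3, treated library 2 or treated library 3 (camera adjusted p = 0.0675, 0.0601, 0.0829 and 0.0521). Among nuclear photosystem subunits 0 of 22 and among Calvin cycle enzymes 0 of 17 passed the limma threshold, also when adjusted over the list alone (camera adjusted p = 0.0925 and 0.977). Camera called the photosystem list upward without control 2 (adjusted p = 0.0249) or treated library 1 (0.00848), and with quantile normalization (0.00293) or the GC correction (0.0418). At an unadjusted p under 0.05 there were 2 and 3 of them, edgeR called 0 of either, and DESeq2 called 0 and 1. Cell cycle and DNA replication genes were lower in 4 of 23 cases and higher in 0, also when adjusted over the list alone (camera adjusted p = 0.000711; adjusted p = 0.421 with an estimated correlation). Their size was small, with CYCB2;4, CYCA1;1 and CDKB2;1 falling by 0.53, 0.56 and 0.49.

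Of 74 named genes 19 lost the call without at least 1 library: TOC1, SDI1, SDI2, BT5, CCR2, CDKB2;1, CHLM, CML38, CYCA1;1, CYCB2;4, TT7, GH3.5, HEMB1, LHCB2.1, MYB12, RVE1, SAUR21, SULTR4;2 and XCP1. They include strongly changed genes such as BT5, whose adjusted p was 0.0526, 0.0805 and 0.0560 without control 1, treated library 1 and treated library 3, and SDI1 (0.0532 without treated library 1). The highest adjusted p without a library was 0.148, for MYB12 without control 2. SAUR21 also lost it with edgeR (adjusted p = 0.0719) and over the other alternatives reached an adjusted p of 0.114 with DESeq2. MYC2, LHCB1.5, MT1A, PR1, SAG12 and SESA1 were listed at 0 in all 6 libraries.

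The authors' deposited table lists 1047 genes as higher and 1057 as lower. Of its 2104 genes 1627 were also tested with limma, all 1627 with the same sign, and 1461 passed the threshold, while 477 lay under the FPKM minimum. Of the 1149 genes called here at least 2-fold, 1131 are in the authors' deposited table. DESeq2 on the recovered reads gave 2105 genes at least 2-fold changed, which included all 2104 of that table.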

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

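All alternatives were fixed before the data were examined except the GC and length corrections, which were chosen after seeing the data and gave 2709 and 2820 genes. Leaving out each library in turn moved the genes changed between 1340 and 3442, the genes higher between 683 and 1944, the genes lower between 657 and 1498, the genes changed at least 2-fold between 884 and 1404 and the gene lists called between 15 and 20. The lowest gene counts came without control 1 and the highest without treated library 2. Without control 2 the values were 1555 genes changed, 781 higher and 774 lower, and without treated library 1 there were 889 higher. What caused these shifts was not tested. A smaller number of samples does not by itself account for the rise from 2696 to 3442 genes without treated library 2. That library stood apart on the second principal component. With a minimum mean of 5 FPKM, which tests fewer genes, 676 genes were lower and 709 changed at least 2-fold. On recovered reads edgeR gave 1924 genes changed at least 2-fold, and DESeq2 gave 2105 and 1830 lower. Both tested more low genes and added no pseudocount of 1. Camera with an estimated correlation called 0 lists, with 1 list at an unadjusted p under 0.05, and fry called 11, 9 of them among the 17. The 8 that fry did not call included the sulfur (fry adjusted p = 0.283), flavonoid (0.189), chlorophyll (0.0886) and abscisic acid (0.0886) lists. The others were the antenna (0.0683), oxidative stress (0.0683), calmodulin-like (0.0683) and ethylene (0.0593) lists. Estimated-correlation adjusted p ran from 0.0571 to 0.547 over the 17 lists.

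No direction of a named gene or list call reversed under any alternative in which it was tested. Over the 14 alternatives that keep all libraries, 2 of the 74 named genes, MYB12 and SAUR21, lost the call where tested, and 14 were not tested at a minimum mean of 5 FPKM. With 1 library left out, 2 of 32 lists lost the camera call and 5 gained it in at least 1 fit. With all libraries kept, camera called 4 further lists under at least 1 alternative (photosystem, heat shock, expansin and aquaporin lists) and fry 2 (metal and vascular lists). Under the scalings tried the median change of all genes stayed between -0.0200 and 0.000895, and the share of higher calls was 55.7% as reported and 52.4% with quantile normalization. Over all alternatives it ran from 49.0% without treated library 1 to 63.0% with a minimum mean of 5 FPKM. Same-numbered control and treated libraries had correlations of their deviations of 0.0861, 0.383 and 0.101. With 3 libraries per group these values cannot tell whether libraries of the same number were paired. The main test, fixed in advance, used no pairing. Control 3 correlated more with treated library 1 (0.302) than with its own number. The replicate block gave 3256 genes changed, 1840 genes higher, 1416 genes lower, 1220 genes changed at least 2-fold and 18 gene lists changed, and moved no count by over 1.5 times. At this depth and sample number the simulated test, with 119 calls, recovered 14.3% of genes changed 1.5-fold (7 of 49). The real data gave 2696 calls, so their threshold was less strict in unadjusted p, and this share does not carry over. Small changes may have been missed, at a rate that is not known.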

Other observations

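All tests in this part were chosen after the result was seen, which for the further root genes means that the value of 1 of them, PRP3, had been seen. Genes of the thalianol cluster on chromosome 5, which makes a triterpene of roots, were singled out after their values were seen. THAS1, CYP708A2, CYP705A5 and BAHD1 fell from 96.7 ± 8.72, 72.8 ± 9.18, 60.4 ± 3.83 and 14.1 ± 1.33 FPKM to 11.8 ± 4.82, 9.31 ± 1.99, 6.56 ± 1.87 and 1.03 ± 0.267 FPKM (limma, all below every control library). MRN1, the synthase of another root triterpene, went from 4.75 to 3.22 FPKM, with an adjusted p of 0.164.

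The fall of root genes was weighed first. A smaller share of root tissue would lower all root-restricted genes by about 1 factor. In a further list of 16 root genes, 10 passed the FPKM minimum, of which 6 were called lower and 2 higher. Their DESeq2 log2 changes varied 6.65 times as much (SD 1.95) as their standard errors. The ratio was 6.08 without PRP3, and 3.33 over all 16, of which 14 were negative. For the root tissue markers, all 10 of them negative, it was 3.55. These values argue against 1 common factor for the listed genes. That the genes are restricted to roots was not checked, and expression elsewhere would make their falls unequal. The ratios therefore cannot decide on a smaller share of root tissue. The root hair gene PRP3 and the endodermal peroxidase gene PER64 fell by 4.69 and 4.24 on the log2 scale, the suberin genes CYP86A1 and GPAT5 had -1.38 and -0.26, and UPB1 and ASFT were at 1.14 and 0.49. Library scaling is argued against, since the median of the 10 root tissue markers was -1.53 after quantile normalization. A smaller share of root tissue, a loss of certain root cells, or a response of root cells to the treatment may underlie the fall, and all stay open.

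The rises in the phosphate starvation, sugar starvation and pattern-triggered immunity lists were weighed against a larger share of shoot tissue, which would raise shoot genes alike. Of the 13 lists camera called upward, these 3 had the highest means (1.06, 1.42 and 1.09). A value above that of the photosystem genes was therefore favoured by the choice. The photosystem genes were taken to follow shoot share alone, which was not tested. Over all 56 tested members, called or not, the log2 changes had a pseudomedian of 1.11 (95% interval 0.804 to 1.39), above the highest change among the 22 photosystem genes (0.44, median 0.14), also without each library in turn; the interval takes genes as independent, although their estimated correlations were 0.52, 0.25 and 0.30 in the 3 lists, and is too narrow to that extent. By list the interval lay above that value for immunity (1.06, from 0.706), also without each library. For phosphate it did so too (1.06, from 0.570), except without treated library 2 (from 0.397 against 0.478). For sugar it did not (1.27, from 0.391 to 2.55), which with all libraries kept rests on PSAG, the highest photosystem gene. The sugar interval also did not lie above without control 2, control 3, treated library 1 or treated library 2. It then began at 0.371, 0.381, 0.226 and 0.386, against 0.598, 0.480, 0.487 and 0.478. PSAG lies 61.4% inside a gene on the other strand and so is uncertain. The next, PSAD2 (0.357, SE 0.153), lies below the sugar interval by less than its standard error. These intervals take correlated genes as independent, and the lists were among those that rose most. They therefore cannot decide on shoot share by themselves. Lists of shoot genes rose less or fell. Mean log2 changes were 0.290 for antenna, 0.233 for chlorophyll synthesis, 0.133 for photosystem and 0.0262 for Calvin cycle genes. For shoot epidermis and guard cell markers the mean was -0.148. Beside these, means of 1.06, 1.42 and 1.09 argue against a larger shoot share as the whole cause. That holds if those shoot genes follow shoot share, which was not tested, and a part from it stays open. Of the 32 members called higher 30 exceeded the highest photosystem change by more than 2 standard errors, which decides nothing since they were chosen for rising, and GC and length corrections left 30 and 32 of them called, which argues against those biases as the whole cause; a response to the treatment may explain the rises and remains a hypothesis.

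Several genes that seedlings usually express were listed at 0 in all 6 libraries, among them MYC2, LHCB1.5 and MT1A. Reads shared with an overlapping gene and left uncounted may be the source. Among protein-coding genes with at least 95% of their span inside another gene, 80.5% (508 of 631) were at 0, against 15.6% (3118 of 19989) of those that overlap none (Fisher's exact test, 2-sided, p = 6.96e-273, genes taken as independent). Among those 1 to 95% inside another gene only 5.79% (406 of 7008) were at 0, and PR1 and SAG12, which overlap no listed gene, were also at 0. Whether any one of these genes was transcribed remains open.

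With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 2696 genes changed, 1502 higher, 1194 lower and 1149 at least 2-fold, each the only 1 of 10 splits to reach its count, and the highest of the other splits gave 0 for each. Each other split mixes control and treated libraries in both groups, which puts treatment difference into the spread within groups. A count of 0 genes was therefore likely there from the outset and says nothing about chance. For gene lists the real split gave 17 and the highest other split 18, and 3 of the 10 splits gave at least 17. Each of the 9 other splits called at least 8 of the 32 lists. Those splits still hold part of the treatment difference, so their list counts do not measure chance either.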
